A study of Homo sapiens with 11 samples.

How the data were processed

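Single-cell RNA-seq was measured in 11 libraries of human trophoblast stem cells: line CT27 on days 0, 3, 6 and 8 of EVT differentiation (2 libraries per day) and the lines CT27, CT29 and CT30 at day 6 (1 library each). Sample labels name the last of these lines CT30, while the series' design text calls it CT20; the labels were followed. Libraries were made with a 10x Genomics 3' kit, per the labels' protocols. Cell Ranger 7.0.1, Seurat 5.2.0 and the genome build GRCh38.p13 are named, per the submitters' processing notes, without the role of each. Filters on cells, doublet removal, integration across libraries and the clustering settings are not given in the sources used here.

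The files analysed were 8 tables, 1 per cluster, of the authors' own comparison of that cluster with all other cells. Per the file headers, each holds the log2 fold change of the average expression, the share of expressing cells in the cluster and in the other cells, a p-value and an adjusted p-value per gene. The deposited p-value times 28927 gives the deposited adjusted p-value in every row below 1, a Bonferroni adjustment, and the name of the test is not given in the sources used here. The deposited shares run from 0 to 1 in steps of 0.1 percentage points and are printed as percent. The tables list only genes with a p-value up to 0.05, a log2 fold change of at least 0.1 in either direction and detection in at least 1% of cells on one side, as tested on the files, so a gene not listed in a table cannot be called unchanged. No column names a library, day, line or number of cells. Sums per library, a test across libraries and an interval for any share were therefore not possible, no library depth can be given, and the planned comparisons of days and lines were not run. The p-values are over cells, which are not replicates, of clusters drawn from the same data, and are too small as evidence of a difference between cultures.

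The tables together listed 17474 genes. XIST and TSIX, where listed, and genes annotated on the Y chromosome alone, 9 in all, were left out, and 17465 were kept. Positions and spans came from the GENCODE release 29 annotation of GRCh38, matched by symbol for 96.1% of the genes; the span is the gene's length on the genome from start to end. It may not be the annotation the authors used. Genes with near-identical copies (metallothioneins, pregnancy-specific glycoproteins, chorionic gonadotropin beta and placental lactogen genes, MHC class I, histones) share reads, so single members are uncertain. Whether the counting used strand is not given in the sources used here, so the antisense genes MYCNOS, LIFR-AS1 and IGFL2-AS1 cannot be told apart from their partners.

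Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A gene was higher in a cluster with an adjusted p under 0.05, a log2 fold change of at least 1 and a share of at least 10% in the cluster, and lower with a log2 fold change of -1 or below and a share of at least 10% in the other cells. Named genes followed a rule fixed before the data were examined: per cluster the 12 largest higher genes with a share of at least 25% and the 6 largest lower ones with a share of at least 25% in the other cells, up to 4 members of each called list, the 8 genes with the largest difference in share in each direction for pairs of clusters named alike, and HLA-G, ITGA6, TP63, MKI67, CGA, ASCL2 and NOTUM throughout. Clone-type identifiers were passed over. The largest adjusted p among the named genes called higher or lower was 0.0189. A list with at least 5 listed members was placed by its median among 10000 random lists of the same size, drawn from genes outside it and matched on the share of expressing cells in 20 bins; it was high at percentile 99.5 or above and low at 0.5 or below. These placements describe the pooled cells and are not tests across samples.

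The share of all cells in each cluster was found by non-negative least squares, because the share of expressing cells outside a cluster is the weighted mean of the shares in the other 7 clusters. The largest residual was 0.0736 percentage points, within the 0.1-point steps of the tables, so the 8 tables come from 1 set of cells. With these weights each fold change was turned into a level relative to the mean of all cells. Weighted levels of the genes in every table summed to a median of 1.0005 (range 1.000 to 1.01) where 1 is exact. On 20 simulated sets of tables with 3972 genes, the largest error was 0.00531 percentage points for a share and 0.00082 on the log2 scale for a level. The simulated fold changes followed the level formula exactly and held no noise, so the level error checks the arithmetic only. In tables of 10750 to 13981 genes, 0 to 4 of 100 simulated lists of 20 genes per cluster were called with no shift, 10 to 91 with 0.5 added to the log2 fold change and 54 to 100 with 1 added. These were placed among fewer random lists than the real ones, matched on the plain mean of both shares.

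Fold changes are relative to average cells, and their median over genes at the 10% share minimum was 0.20 in qCTB, 0.17 in mEVT, 0.27 in aCTB, -0.34 in pEVT, -0.11 in pBTB, -0.42 in pSTB, -0.39 in hsEVT and 0.26 in eCTB. Centring on these medians left the sign of every called list's median as it was. Alternatives listed before the data were examined were a log2 minimum of 0.5, share minimums of none and 25%, a share difference of 10 points in place of the fold change, unmatched random lists, the mean in place of the median, lists without low-share or multiply listed members, the 200 largest genes for overlaps, and other gene sets for the cluster shares. Centring, leaving mEVT and hsEVT out of the other cells, and matching on gene span were chosen after seeing the data. The fold changes without mEVT and hsEVT were worked out from the levels and are approximate. A gene not listed for mEVT or hsEVT was given the mean level of all cells there. Genes with no positive level left were dropped, and the authors' adjusted p and shares were kept.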

Results

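Human trophoblast stem cells are cultured progenitors of the placental epithelium that can be directed to become extravillous trophoblast (EVT), the lineage that invades the uterine wall. The series followed this differentiation with droplet-based single-cell RNA sequencing in 11 libraries. Line CT27 was sampled in the stem state on day 0 and on days 3, 6 and 8 of EVT differentiation, with 2 libraries per day, and the lines CT27, CT29 and CT30 were sampled at day 6 with 1 library each. The values analysed were the authors' 8 deposited tables, each of which compares 1 cluster of cells with all other cells and pools the libraries. Of the cluster names 3 end in CTB (cytotrophoblast, the progenitor layer), another 3 end in EVT, 1 ends in STB (syncytiotrophoblast, the fused hormone-secreting layer) and 1 ends in BTB, which the labels do not spell out. The tables carry no library, day or line, so the days and the lines were not compared here, the values have no replicate error, and the depth per library is unknown.

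The question the tables address is which genes set each cell state apart. A gene was called higher or lower by a rule of size: an authors' adjusted p under 0.05, a log2 fold change of at least 1 in either direction, and detection in at least 10% of the cells on the higher side. The authors' p-values were computed over cells, which are not replicates, and the clusters were drawn from the same expression values, so the p served only as a floor. Each of 30 gene lists fixed before the data were examined was placed by the median log2 fold change of its listed members among 10000 random lists matched on detection. It is called high or low where it lay in the outer 0.5% on that side. Of 210 placements 109 were called, against 2.1 for lists of genes drawn at random. The lists share members and each cluster is among the other cells of the rest, so the placements are not independent and 2.1 is only a reference. The cluster names are the authors' own, and the marker genes behind them are not given in the sources used here, so the CTB, EVT and STB lists are no independent evidence for the names.

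The 8 clusters held between 3.52% and 18.7% of all cells, as worked out from the shares of expressing cells in the authors' deposited tables. The largest was qCTB, followed by mEVT with 15.2%, aCTB with 14.0%, pEVT with 13.7%, pBTB with 12.1%, pSTB with 11.6%, hsEVT with 11.3% and eCTB with 3.52%. Detection differed widely among them. Of the 3972 genes listed in every table, a cell of eCTB expressed 1160 on average, a cell of aCTB 1147 and a cell of qCTB 1076, whereas a cell of mEVT expressed 661 and a cell of hsEVT only 179. Shares of expressing cells are therefore not on an equal footing across clusters, and the level of free RNA in the droplets is not known.

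**Figure D1:**
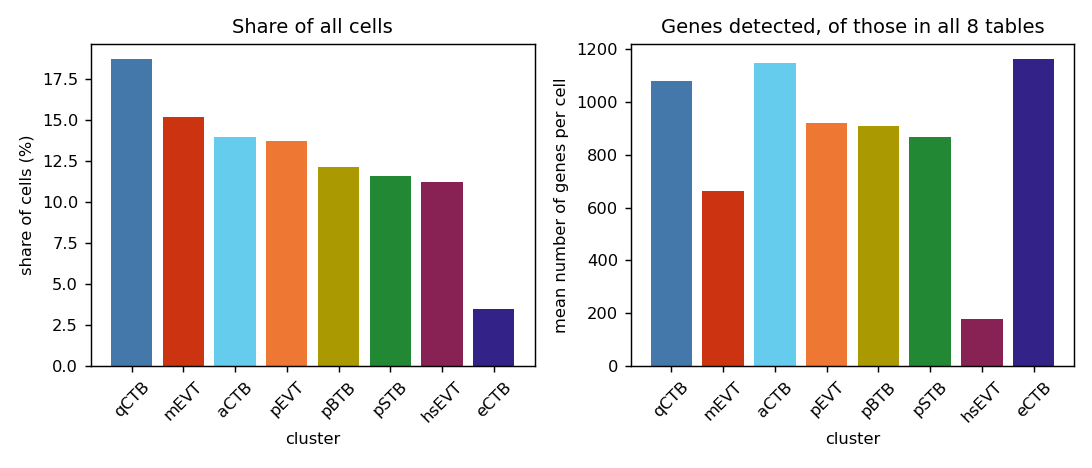
Share of all cells (left, percent) and mean number of genes detected per cell among the 3972 genes listed in every table (right) for each of the 8 clusters, with 1 bar per cluster. hsEVT holds 11.3% of the cells but shows 179 of these genes per cell, against 1160 in eCTB.

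HLA-G and 6 other genes fixed beforehand were followed through all clusters. HLA-G, the non-classical MHC class I molecule of EVT (chromosome 6, 29826967 to 29831125), was detected in 97.0% of pEVT, 88.0% of mEVT and 72.4% of hsEVT cells in the authors' deposited tables, against 32.4% of qCTB, 22.7% of aCTB, 35.4% of eCTB and 55.8% of pSTB cells. NOTUM, a secreted enzyme that inactivates WNT proteins, followed the same order, from 91.7% of pEVT cells to 5.7% of aCTB cells. By level, HLA-G was highest in hsEVT, at 2.59 times the mean of all cells against 2.17 in pEVT and 1.80 in mEVT. ASCL2, a transcription factor of the EVT lineage, was detected in 95.5% of pEVT and 81.7% of pBTB cells and in 30.7% of hsEVT cells, where its level was still 1.96 times the mean of all cells. TP63, a transcription factor of epithelial stem cells, was found in 40.1% of qCTB and 28.5% of aCTB cells, but in 7.2% of eCTB cells and 2.4% of pEVT cells. The proliferation marker MKI67 was detected in 74.0% of aCTB, 62.7% of eCTB and 61.8% of pBTB cells, and in 8.4% of pEVT cells. The integrin ITGA6 was detected in 78.4% of qCTB and 8.5% of hsEVT cells, at 1.76 and 0.798 times the mean level of all cells. Its level in pEVT was lower still, at 0.590, although 55.9% of those cells expressed it. CGA, the alpha subunit of chorionic gonadotropin, was detected in 99.9% of pSTB cells at 5.06 times the mean level of all cells. It was also detected in 99.9% of pEVT and 98.9% of mEVT cells at 0.501 and 0.256 times that mean, so its detection alone does not separate these clusters.

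**Figure D2:**
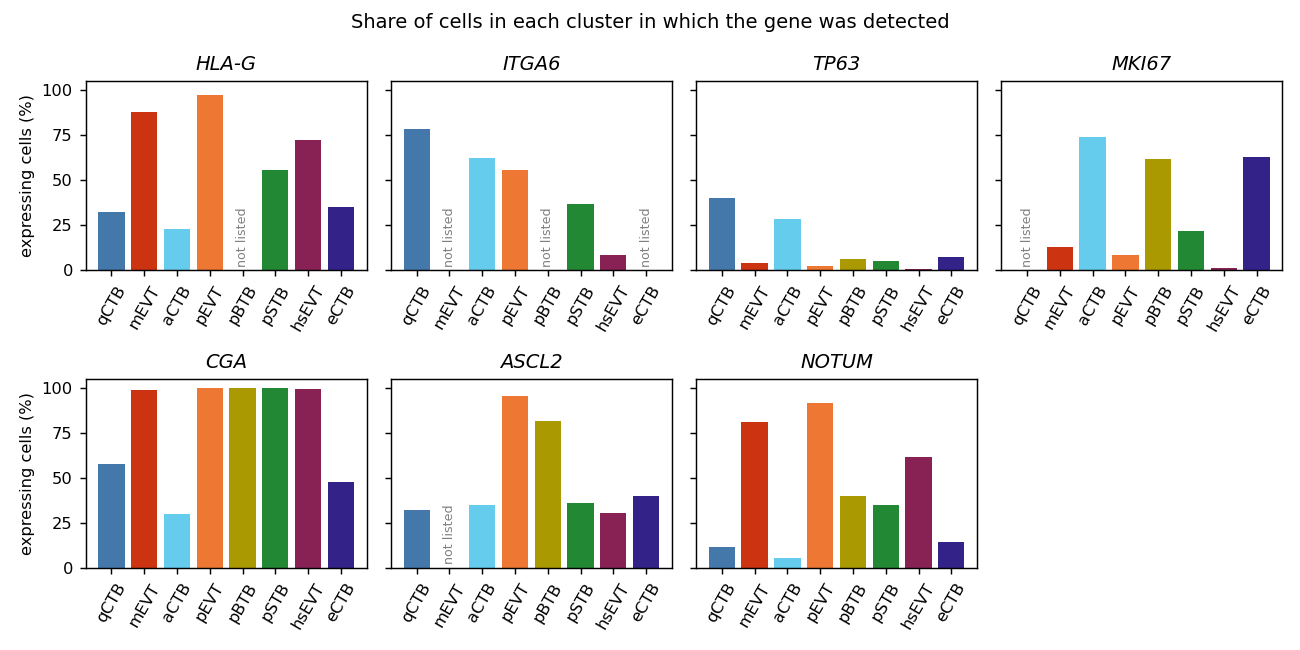
Share of cells of each cluster (percent, 1 bar per cluster) in which HLA-G, ITGA6, TP63, MKI67, CGA, ASCL2 and NOTUM were detected, from the authors' deposited tables; "not listed" marks a gene that a table leaves out, not a share of 0. HLA-G reaches 97.0% in pEVT and TP63 reaches 40.1% in qCTB.

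Cluster qCTB was marked by stem-state and epithelial junction genes, and by low EVT genes. In the authors' deposited table, KRT17, an epithelial keratin (chromosome 17, 41619441 to 41624842), was 13.1-fold higher and detected in 37.3% of its cells against 4.9% of other cells. TP63 (chromosome 3, 189631416 to 189897279) was 5.70-fold higher, and GPRC5A, C19orf33, the natriuretic peptide gene NPPB and the actin-binding gene TAGLN had log2 fold changes of 3.57, 3.51, 3.46 and 3.06. The cytotrophoblast and stem state list was high, with 12 of 19 listed members higher and 1 lower and a median log2 fold change of 1.35; TP63, PAGE4 (2.31) and the endocytic receptor LRP2 (1.58) were among the 12. Its lower member was the cyclin gene CCNE1 (-1.69). Of 20 epithelial junction genes 6 were higher and none was lower, led by the integrin ITGB4 (1.94), OCLN (1.88), EPCAM (1.53) and CLDN6 (1.52). The fibroblast and stroma list was also high, on 5 listed members, of which COL1A2 (2.80), COL1A1 (1.69) and TWIST1 (1.28) were higher.

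The EVT list was low in qCTB, with 20 of 28 listed members lower and a median log2 fold change of -3.12. ADAM12, a metalloprotease, stood at -5.45, the laminin chain LAMA4 at -5.11, NOTUM at -4.63 and the serine protease HTRA4 at -4.52 in the authors' deposited table. STB genes (15 of 28 lower), interferon response genes (6 of 22 lower) and MHC class I genes (5 of 13 lower, HLA-G at -3.56) were low as well. The matrix and proteolysis list was low, with 17 of 35 lower and 4 higher (median -1.04), although COL1A1 and COL1A2 of the stroma list were higher. The S phase and G2/M lists had no member past the rule in either direction. In all, 734 genes were higher and 574 lower, and 512 and 758 once the fold changes were centred on their median. The high WNT target list (4 of 7 higher, 1 lower) rested on the median, since the mean of its members placed it at percentile 45.5, and it ended at 98.3 when mEVT and hsEVT were left out of the other cells.

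Cluster aCTB was marked by genes of the cell cycle. The G2/M list was high, with 45 of 52 members higher, none lower and a median log2 fold change of 1.60, and the S phase list followed with 30 of 42 higher and a median of 1.16. Among them were the mitotic kinase NEK2 (2.11), TACC3 (1.90), the replication factor GINS2 (2.03) and UHRF1 (2.00), from the authors' deposited table. Among the higher genes detected in at least 25% of its cells, the largest fold changes were those of the ephrin receptor EPHA4 (chromosome 2, 221418027 to 221574202), 11.7-fold higher and detected in 27.1% of cells against 2.8%, and of the linker histone HIST1H1A, with a log2 fold change of 3.46. The non-coding LINC00379 (2.96), the transcription factor HAND1 (2.88), EMP2 (2.82), NLRP7 (2.80), the connexin GJA1 (2.68) and CADM1 (2.64) were also higher. Cholesterol synthesis genes (EBP at 1.01, HSD17B7 at 1.10; 2 of 17 higher) and mitochondrially encoded genes (3 of 12 higher, MT-ND6 at 1.57) were high at smaller medians of 0.66 and 0.58.

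The EVT list was low in aCTB, where 21 of 28 listed members were lower, none was higher and the median log2 fold change was -4.72. In the authors' deposited table ADAM12 stood at -7.33, the metalloproteinase PAPPA at -7.01, HTRA4 at -6.78 and LAMA4 at -6.69. STB genes were low too (20 of 30 lower, median -4.44), including the placental lactogen gene CSH1 at -6.52 and PSG3 at -6.10. Among interferon response genes 9 of 23 were lower, and among MHC class I genes 7 of 13, with HLA-G at -4.57 and B2M at -2.16. Counts were 1092 higher and 1079 lower, and 659 and 1461 after centring. The cholesterol and mitochondrial calls ended when random lists were also matched on gene span (percentiles 99.3 and 95.3) and when they were not matched at all (97.2 and 91.4).

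Cluster eCTB, the smallest, was marked by PASD1 and by cell cycle genes. PASD1 (chromosome X, 151563622 to 151676739) was 29.8-fold higher in the authors' deposited table and detected in 44.9% of its cells against 1.6% of other cells. The antisense transcript IGFL2-AS1 was 11.2-fold higher, and PINCR (3.17), LINC00624 (2.81), CALN1 (2.67), the meiotic cohesin STAG3 (2.51), the growth factor BMP6 (2.38) and the gastrin receptor CCKBR (2.30) followed, of which CCKBR was detected in 73.3% of aCTB cells as well. G2/M genes were high with 15 of 52 higher and none lower (BUB1 at 1.18, TACC3 at 1.17), S phase genes with 4 of 41 higher (UHRF1 at 1.29), and p53 targets with 3 of 13 higher and 1 lower. FDXR (1.40), ZMAT3 (1.05) and the death receptor gene TNFRSF10B (1.04) were the p53 targets that were higher, and GDF15 (-1.18) was lower. Epithelial junction genes were high with 4 of 15 higher and 1 lower (GJA1 at 1.47, EPCAM at 1.16, OCLN at 1.16; DSC2 at -1.47). EVT genes were low, with 21 of 27 lower and a median of -3.49, as were STB genes with 17 of 30 lower. The 589 higher and 701 lower genes became 306 and 912 after centring, and 280 and 455 when mEVT and hsEVT were left out of the other cells. The p53 call ended without matching of the random lists (percentile 99.3) and by the mean (99.1), and the junction call without matching (85.3) and with members under a 10% share left out (99.3).

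Cluster pEVT combined EVT, interferon and metallothionein genes. Of 28 EVT genes 14 were higher and 2 lower (median log2 fold change 1.11), among them NOTUM (chromosome 17, 81952507 to 81961840), 3.48-fold higher, ASCL2, 2.80-fold higher, and the protease inhibitor SERPINE2 at 1.51 in the authors' deposited table. The enzyme gene PIPOX was 4.20-fold higher and detected in 30.4% of cells against 4.1%. The zinc-binding metallothionein genes MT1H (2.01), MT1X (1.80) and MT1G (1.80), PDE6H (1.99) and the myosin light chain MYL4 (1.86) were also among its leading genes. Interferon response genes were high with 11 of 22 higher and none lower (PSMB8 at 2.11, IFI27 at 1.73, IFIT5 at 1.48), and MHC class I genes with 6 of 12 higher (TAP1 at 1.49, HLA-G at 1.41). The 2 lower EVT genes included TNFRSF1B (-3.26).

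Cell cycle and progenitor genes were lower in pEVT. None of the 52 G2/M genes was higher and 42 were lower (median -2.48; HJURP at -3.54, KIF2C at -3.44), as were 35 of 41 S phase genes. Of 19 cytotrophoblast genes 12 were lower, with LRP2 at -7.37, BMP7 at -4.34 and TP63 at -3.55 in the authors' deposited table. The amino acid and nutrient transport list was low with 9 of 14 lower (the iron exporter SLC40A1 at -3.72, SLC7A8 at -3.70), and steroidogenesis genes with 5 of 9 lower (CYP19A1 at -4.07). The counts of 226 higher and 1426 lower genes became 561 and 959 after centring, and 722 and 1708 when mEVT and hsEVT were left out of the other cells. The high position of the column and EVT precursor list (3 of 14 higher, 3 lower, median 0.36, mean -0.49) turned to percentile 34.4 by the mean and ended at 89.3 without members of other lists, and the steroidogenesis call ended at 0.93 without matching.

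Cluster mEVT carried EVT and matrix genes together with long and nuclear RNAs. ADAM12 (chromosome 10, 126012381 to 126388455) was 7.62-fold higher and detected in 83.6% of its cells against 32.7%, LAMA4 was 6.90-fold and fibronectin (FN1) 6.83-fold higher in the authors' deposited table. Of 26 EVT genes 16 were higher and 3 lower (median log2 fold change 1.49), and 17 of 32 matrix and proteolysis genes were higher, COL4A1 (2.37) among them. The non-coding MYCNOS (3.42) and LIFR-AS1 (3.28), SHOC1 (3.49), GDPD4 (3.38) and PCED1B (3.04) were among its higher genes. Interferon response (8 of 20 higher; DDX58 at 2.30, STAT2 at 2.08) and MHC class I genes (7 of 12 higher; HLA-F at 2.93, TAP2 at 1.83) were high. Nuclear-retained RNAs were high as well, with 4 of 6 higher, including MALAT1 (1.95), KCNQ1OT1 (2.04) and SNHG14 (2.06).

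Ribosomal protein genes were lower in mEVT almost without exception: 81 of 82 were lower, at a median log2 fold change of -2.00, with RPS8 at -2.49 in the authors' deposited table. G2/M genes (26 of 50 lower), S phase genes (17 of 40 lower, 1 higher), cytotrophoblast genes (9 of 19 lower), p53 targets (6 of 13 lower; CDKN1A at -2.91) and STB genes (8 of 27 lower, 2 higher) were low. TUBB2B (-6.28), S100A16 (-6.12) and the fatty acid carrier FABP5 (-5.00) were among the lower genes. Fold change rose with gene span across 8620 genes (Spearman's rho 0.59; genes are not independent replicates), from a median of -1.34 for genes under 10 kb to 1.04 for genes of 100 kb or more, and in the other 7 clusters rho lay between -0.40 and -0.10. In all, 2094 genes were higher and 2092 lower, and 1634 and 2445 after centring. Long non-coding RNAs made up 14.0% of the 2033 higher genes with an annotated type against 5.24% of the 8620 annotated genes at the 10% share minimum. The interferon, MHC class I, cytotrophoblast and p53 calls ended when members under a 10% share were left out (percentiles 99.3, 97.7, 0.97 and 0.66). The MHC class I call also ended without matching (98.95), and the p53 call without members of other lists (11.3).

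**Figure D3:**
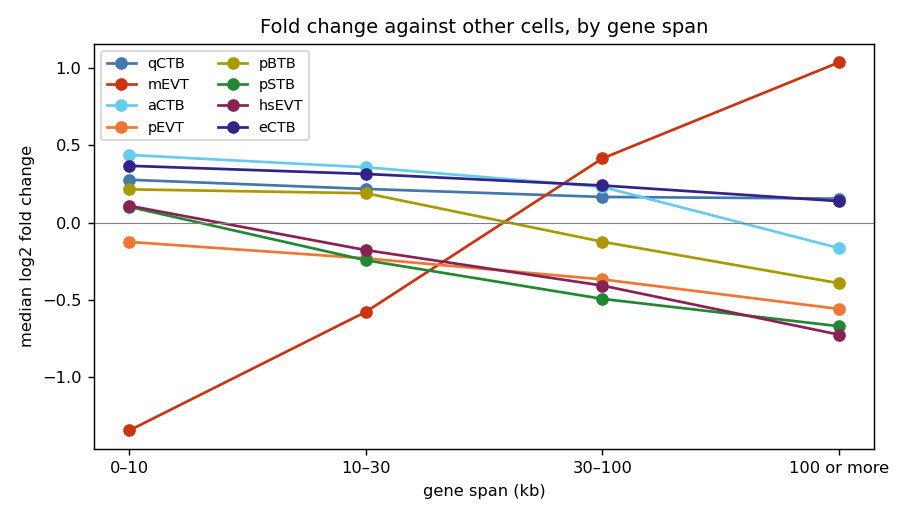
Median log2 fold change against all other cells (vertical axis) of genes grouped by the span of the gene in kb (horizontal axis), with 1 line per cluster and genes detected in at least 10% of cells on either side. mEVT climbs from -1.34 to 1.04 while hsEVT goes from 0.11 to -0.72.

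Cluster hsEVT kept a small EVT and interferon profile on very sparse detection. IFI27, an interferon-induced gene (chromosome 14, 94104836 to 94116698), was 5.45-fold higher, CSH1 4.62-fold, the matrix protein gene SPARC 3.96-fold and HLA-G 3.25-fold higher in the authors' deposited table. C15orf48 (2.31), the imprinted RNA H19 (1.88), ISG15 (1.84) and the coagulation inhibitor TFPI (1.78) were also higher. Higher were 8 of 27 EVT genes (median log2 fold change 0.74), 4 of 21 interferon response genes, 3 of 12 MHC class I genes and 3 of 26 STB genes. No member of these 4 lists was lower, and all 4 lists were high. G2/M (39 of 49 lower), S phase (21 of 42), cytotrophoblast (9 of 19; LRP2 at -4.43, TEAD4 at -3.11) and mitochondrially encoded genes (9 of 13; MT-ND1 at -1.67) were low.

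Detection in hsEVT went against the fold changes. Of the 2452 genes with a positive log2 fold change at the 10% share minimum, 2435 (99.3%) were detected in a smaller share of hsEVT cells than of other cells, against 39.3% in mEVT and at most 0.0362% in the other 6 clusters. ISG15, for example, was 1.84 higher on the log2 scale while detected in 62.2% of hsEVT cells and 76.6% of other cells in the authors' deposited table. The counts were 86 higher and 1326 lower genes, 284 and 623 after centring, and 130 and 1221 when mEVT was left out of the other cells. The ribosomal protein list, high at a median of 0.31 with no member past the rule, fell to percentile 90.2 when mEVT was left out of the other cells, 97.4 without members under a 10% share and 97.7 when matched on gene span.

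Cluster pSTB was set apart by STB genes. RHOBTB1 was 39.0-fold higher in the authors' deposited table, and aromatase (CYP19A1, chromosome 15, 51208057 to 51338610) was 34.0-fold higher and detected in 94.1% of its cells against 12.4%. HOPX was 26.8-fold, HSD11B2, which inactivates cortisol, 25.8-fold and CGA 10.8-fold higher. Of 30 STB genes 22 were higher and 2 lower, with a median log2 fold change of 2.88. Stress response genes were high with 8 of 20 higher and none lower (CHAC1 at 3.68, DDIT4 at 2.67, DDIT3 at 2.61, ATF3 at 1.97), nutrient transport with 7 of 15 higher and 2 lower (SLC40A1 at 4.50, SLC43A2 at 3.42, the glucose transporter SLC2A1 at 2.02), and steroidogenesis with 5 of 11 higher (CYP11A1 at 2.25, FDX1 at 2.24). Among TGF-beta targets, ID2 (3.31) and SMAD7 (3.02) were higher and CCN1 (-1.62) was lower.

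G2/M genes were low in pSTB, with 34 of 50 lower and 1 higher, and WNT targets were low with 3 of 7 lower, the receptor-degrading ligase ZNRF3 at -2.42 in the authors' deposited table. MHC class I (5 of 13 lower; HLA-G at -1.48), interferon response (4 of 22 lower, 1 higher) and column genes (6 of 13 lower) were low at medians of -1.31, -1.34 and -1.27. The 761 higher and 1640 lower genes became 1297 and 672 after centring. When mEVT and hsEVT were left out of the other cells, the interferon, MHC class I, matrix and column lists were no longer low (percentiles 33.1, 11.8, 86.6 and 4.46). The steroidogenesis call ended under 4 alternatives (percentiles 98.6 unmatched, 96.6 without members of other lists, 99.2 with those clusters left out, 99.1 matched on span), and the TGF-beta call by the mean (99.4) and without members of other lists (99.2).

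Cluster pBTB had few higher genes, with cell cycle genes among them. Cyclin B1 (CCNB1, chromosome 5, 69167010 to 69178245) was 4.07-fold higher and detected in 97.3% of its cells against 58.9% in the authors' deposited table. The ribonucleotide reductase subunit RRM2 was 3.54-fold and the signalling gene WNT10B 3.50-fold higher, followed by CDK1 (1.37), HMGB2 (1.37) and ID3 (1.34). G2/M genes (12 of 51 higher, none lower, median log2 fold change 0.78) and S phase genes (6 of 40 higher, none lower, median 0.78) were high. EVT genes were low with 9 of 22 lower (PAPPA at -3.50, NOTUM at -2.15), STB genes with 8 of 28 lower (CYP19A1 at -2.40) and interferon response genes with 8 of 22 lower (IFI27 at -2.61). Cytotrophoblast genes were low at a median of -0.54, with 6 of 16 lower, including LRP2 (-4.22), EGFR (-1.70) and TP63 (-1.61). In all, 76 genes were higher and 564 lower, and 129 and 478 after centring. With mEVT and hsEVT left out of the other cells 94 genes were higher, of which 32 were among the 76, and the cytotrophoblast call ended without matching (percentile 15.4), without members of other lists (7.32) and when matched on gene span (0.61).

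**Figure D4:**
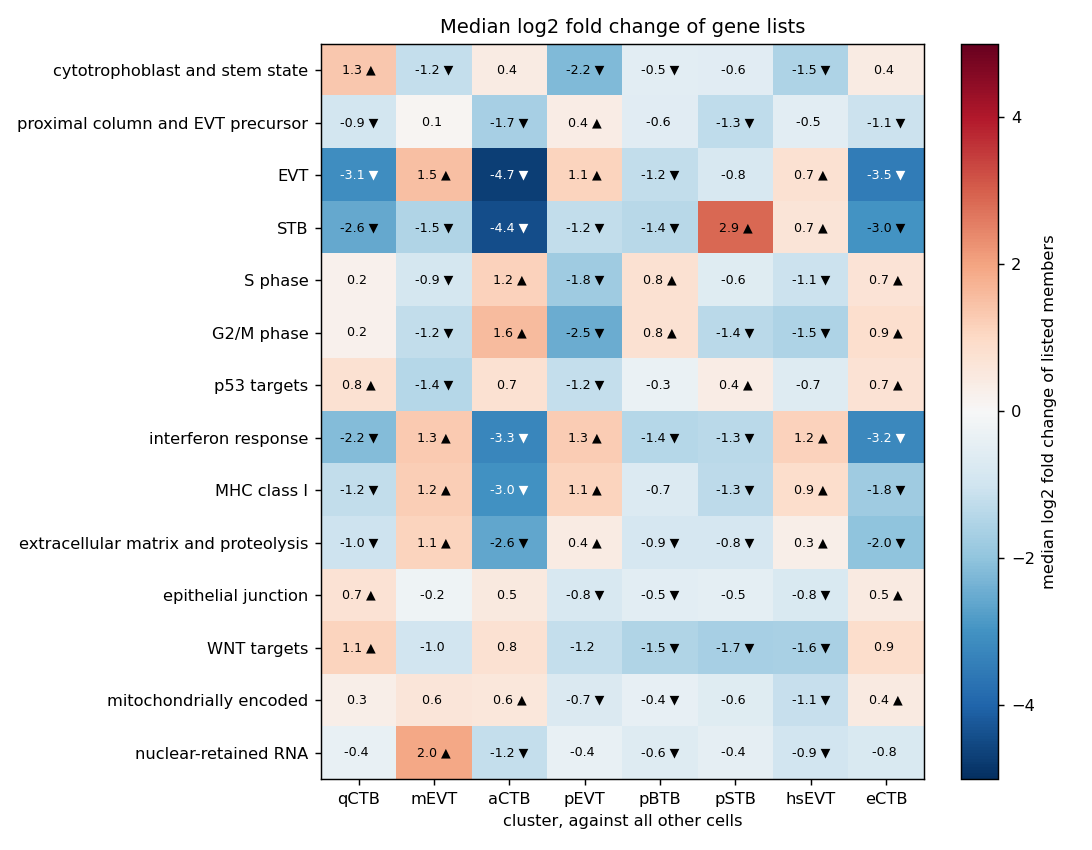
Median log2 fold change of the listed members (colour and number) of the gene lists called in at least 4 of the 8 clusters (rows), in each cluster against all other cells (columns), from the authors' deposited tables; triangles pointing up mark high and pointing down low lists. EVT genes are high in mEVT, pEVT and hsEVT and STB genes reach 2.88 in pSTB.

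Clusters whose names end alike were also set side by side, gene by gene, with no test because there are no replicates. Between pEVT and mEVT, 1306 of 10809 genes were detected in a share of cells at least 25 points higher in pEVT and 1 in a share as much lower. MT1X was detected in 86.5% of pEVT and 20.7% of mEVT cells, GABARAP, an autophagy gene, in 94.3% and 31.1%, and RNF7 in 87.1% and 25.3%, from the authors' deposited tables. SHOC1 (16.0% and 35.4%) and LIFR-AS1 (70.9% and 86.9%) went the other way. Levels followed these large differences in share. Of the 1306 genes 1286 also had a higher level in pEVT, and the 1 gene with the lower share had a lower level. Beyond the large differences, shares and levels leaned in opposite directions. The share was higher in pEVT by any amount for 7683 of the 10809 genes. By level, 998 genes were at least 2-fold higher in pEVT and 2068 at least 2-fold lower. The median log2 ratio of pEVT over mEVT was -0.72. By level, the ribosomal protein list was higher in pEVT, with all 73 genes listed in both more than 2-fold higher and a median log2 ratio of 2.07, and nuclear-retained RNAs were lower at a median of -1.73. The EVT list was not called in this comparison. The hypoxia and glycolysis list was placed high in pEVT at a median of 0.50, but it was split, with 14 of 26 above 0 and 6 below -1. These placements were not matched on gene span, with which the fold changes in mEVT rose.

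Between hsEVT and mEVT, no gene had a share at least 25 points higher in hsEVT and 2339 of 12202 had a share as much lower, JMJD1C (13.7% of hsEVT and 91.8% of mEVT cells) and TBC1D5 (12.2% and 89.0%) among them in the authors' deposited tables. By level, all 63 ribosomal protein genes listed in both were higher in hsEVT (median log2 ratio 2.08), as were 21 of 23 STB genes (1.86) and 19 of 26 hypoxia and glycolysis genes (0.93). Nuclear-retained RNAs were lower in hsEVT at a median of -2.24. These placements were not matched on gene span either.

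Against pEVT, hsEVT had no gene with a share at least 25 points higher and 3731 of 11002 with a share as much lower, such as TIAM1 (16.5% of hsEVT and 92.4% of pEVT cells) and MACF1 (20.7% and 95.1%) in the authors' deposited tables. Levels differed far less among genes with a share of at least 10% in either cluster. Of these, 78 were at least 2-fold higher in hsEVT and 34 at least 2-fold lower. Genes rarer in both clusters, such as INSL4 and LGALS16, were not counted. The median log2 ratio over all 11002 genes was 0.08. STB genes were higher in hsEVT at a median log2 ratio of 1.52, with 21 of 23 above 0, and G2/M genes at 1.06 with 47 of 49 above 0. The shift was broad: nutrient transport (median 1.03), steroidogenesis (0.71), p53 target (0.60), S phase (0.58) and cytotrophoblast genes (0.51, 15 of 18 above 0) were also higher, as were 4 further lists. INSL4 (log2 ratio 3.70), LGALS16 (3.76) and CYP19A1 (3.57), genes expressed in STB, were among the named genes. Their shares hardly differed, at 9.8%, 7.7% and 12.5% of hsEVT and 8.7%, 6.3% and 11.8% of pEVT cells. MKI67, a G2/M gene, was detected in 1.5% of hsEVT and 8.4% of pEVT cells. Its level went the other way, at 0.280 and 0.124 times the mean of all cells. Mitochondrially encoded genes were lower in hsEVT than in pEVT (median -0.48).

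Among the CTB-named clusters, lists of differentiated trophoblast and of the cell cycle differed, and the epithelial junction list was called in none of the 3 pairs. Against qCTB, aCTB had all 36 G2/M and all 23 S phase genes listed in both at a higher level (median log2 ratios 1.04 and 0.92). STB (median -1.92, 25 of 28 at least 2-fold lower), EVT (-1.51), interferon response (-1.35) and matrix genes (-1.13) were lower in aCTB, and HMMR was detected in 67.9% of aCTB and 36.6% of qCTB cells in the authors' deposited tables. SERPINE1 (11.2% and 46.4%), S100P (23.5% and 56.5%) and the cell cycle inhibitor CDKN1C (46.3% and 72.9%) were detected less often in aCTB. The adhesion receptor ADGRL3 was detected in 25.7% of eCTB, 89.3% of qCTB and 82.5% of aCTB cells, and the desmosomal cadherin DSC3 in 13%, 48% and 51.1%. TP63 was detected in 7.2% of eCTB and 40.1% of qCTB cells, and DSG3 in 3.9% and 35.6%. PASD1 was detected in 44.9% of eCTB cells, 2.0% of qCTB and 0.9% of aCTB cells. Between eCTB and aCTB the G2/M list was lower in eCTB (median log2 ratio -0.38) and the STB and EVT lists higher (1.27 and 1.02), although both clusters lay below the other cells for these genes. Against qCTB, eCTB was higher for G2/M (0.61) and S phase genes (0.56) and lower for STB (-0.80), interferon response (-0.55), matrix (-0.48) and EVT genes (-0.47).

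Higher genes were shared along the CTB and EVT names. Of the genes higher in aCTB, 417 were also higher in eCTB and 383 in qCTB, against 59.4 and 67.3 for independent lists, and 295 were shared by qCTB and eCTB against 41.5. pEVT and hsEVT shared 48 higher genes against 1.71, and mEVT and pEVT 72 against 31.0. mEVT and hsEVT shared 15 against 11.9, and none among the 200 largest of each. aCTB and pBTB shared 39 against 8.13. Each cluster belongs to the other cells of the next, which by itself pulls such overlaps below those of independent lists.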

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

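Centring, leaving mEVT and hsEVT out of the other cells and matching on gene span were chosen after seeing the data. No paired analysis was possible because the tables hold no column per library, and leaving out each replicate in turn was not run for the same reason. The depth of the libraries is unknown and its effect on a count could not be measured. Counts of higher and lower genes moved with the thresholds by the construction of those thresholds. With a log2 minimum of 0.5 the higher genes were 1739 in qCTB, 2983 in aCTB, 878 in pEVT, 657 in pBTB, 1446 in pSTB, 370 in hsEVT and 2280 in eCTB, and the lower genes 1122 in qCTB, 3174 in mEVT, 1755 in aCTB, 2815 in pEVT, 1454 in pBTB, 3498 in pSTB and 3548 in hsEVT. With no share minimum there were 1620 higher in qCTB, 3653 in mEVT, 2032 in aCTB, 353 in pEVT, 148 in pBTB, 1475 in pSTB, 384 in hsEVT and 1399 in eCTB, and 1204 lower in qCTB, 3252 in mEVT, 2084 in aCTB, 3283 in pEVT, 1938 in pBTB, 3362 in pSTB, 3212 in hsEVT and 1120 in eCTB. At a share minimum of 25% higher genes came to 409 in qCTB, 1348 in mEVT, 47 in pBTB, 41 in hsEVT and 327 in eCTB, and lower genes to 334 in qCTB, 647 in aCTB, 622 in pEVT, 176 in pBTB, 768 in pSTB, 639 in hsEVT and 409 in eCTB. A share difference of 10 points in place of the fold change gave 2995 higher genes in qCTB, 1021 in mEVT, 4082 in aCTB, 2449 in pEVT, 1775 in pBTB, 1931 in pSTB, 10 in hsEVT and 3856 in eCTB, and 258 lower in qCTB, 3628 in mEVT, 523 in aCTB, 692 in pEVT, 233 in pBTB, 834 in pSTB, 7999 in hsEVT and 299 in eCTB. Centring on the median gave 659 higher in aCTB, 561 in pEVT, 129 in pBTB, 1297 in pSTB, 284 in hsEVT and 306 in eCTB, and 672 lower in pSTB and 623 in hsEVT. Leaving mEVT and hsEVT out of the other cells gave 722 higher in pEVT (all 226 of the original ones among them), 130 in hsEVT and 280 in eCTB, and 336 lower in qCTB and 455 in eCTB. The other counts stayed within 1.5 times, but the genes changed more than the counts in pBTB, where 32 of the 76 were still higher; in eCTB 273 of the 589 were.

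Lists called came to 9 in qCTB by the mean in place of the median (14 by the median), 7 in mEVT with members under a 10% share left out (12 before) and 9 in pSTB without members of other lists (14 before), and stayed within 1.5 times in the remaining combinations. Of the 109 calls 61 held under every alternative run and 48 ended under at least 1. A call left with fewer than 5 members by an alternative could not be placed again there and was not counted as ended. Among single placements, the mean turned the column list in pEVT to percentile 34.4 and the WNT target list in qCTB to 45.5, since single members lie far below the others (SOX15 at -4.49 and NOTUM at -4.63). Without mEVT and hsEVT in the other cells, the matrix list in pSTB turned to percentile 86.6; the cause was not tested. The overlap over independent lists went from 1.26 to 0 for mEVT and hsEVT, from 1.03 to 0 for pBTB and eCTB and from 1.08 to 0.826 for pSTB and hsEVT with the 200 largest genes of each, and from 0.645 to 1.37 for pEVT and pBTB and from 0 to 1.14 for pBTB and hsEVT at a log2 minimum of 0.5. The remaining overlaps kept their side of 1, and the cluster shares stayed the same within rounding whether fitted from each table alone or from genes detected in at least 10% of every cluster.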

Other observations

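Tests chosen only after the result was seen were those of counts per cell, damaged cells, nuclear RNA, depth, chromosomes and genes below both aCTB and qCTB, and the 3 gene families of the next paragraph were also picked after the data were examined.

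The 8 metallothionein genes, which bind zinc and copper, differed among the EVT-named clusters and were also high in pBTB. They had a median log2 fold change of 1.63 in pEVT (4 of 8 higher), 1.00 in hsEVT (3 of 8 higher) and 0.71 in pBTB (1 of 7 listed higher, none lower), but -1.17 in mEVT (4 of 8 lower) and -1.79 in qCTB (4 of 8 lower), from the authors' deposited tables. Replication histone genes were higher in 15 of 54 listed members in aCTB at a median of 1.86, 6 of 50 in eCTB at 0.99 and 6 of 46 in pBTB at 0.91, and had medians of -2.79 in mEVT and -2.58 in pEVT; in pSTB, where the G2/M list was low, 5 of 43 were higher and 5 lower at a median of -1.09. Polyadenylated histone transcripts are a small part of the total, since most replication histone RNAs lack a poly(A) tail. Pregnancy-specific glycoprotein genes were higher in pSTB (6 of 9, median 1.85) and in hsEVT (3 of 7 listed, median 1.21) and lower in aCTB (6 of 9, median -4.49).

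Shares did not set CSH1 in hsEVT apart from the EVT-named mEVT (90.1% and 88.3% of cells), while its level did, at 3.28 and 1.36 times the mean of all cells. Genes of hypoxia and glycolysis and of heat shock were called in no cluster against all other cells, but they were called between clusters. The hypoxia and glycolysis list lay high against mEVT in pEVT (14 of 26 above 0, 6 below -1) and in hsEVT (19 of 26 above 0, 3 below -1). Neither placement was matched on gene span, and short genes were low in mEVT, so an effect of span is not excluded. Heat shock genes were higher in aCTB than in qCTB (median log2 ratio 0.41, 11 of 13 above 0), higher in hsEVT than in pEVT (0.29, 12 of 13) and lower in eCTB than in aCTB (-0.20, 0 of 14 above 0). Of the lists for other cell types, the amnion list was placed in 3 clusters and called in none, immune cells and primed pluripotency had too few listed members to be placed, and the endothelium list, which holds CDH5, was low in qCTB and aCTB on 6 listed members, of which 0 passed the rule in qCTB and 1 was lower in aCTB; by the mean the qCTB call ended (percentile 2.32).

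The low detection in hsEVT cannot be told apart from fewer counts per cell. The 99.3% of its genes with a positive log2 fold change that were detected in a smaller share of hsEVT cells are the pattern itself, and no table gives counts per cell. Droplets filled with free RNA averaged over all cells are argued against, since the genes higher in aCTB had a median log2 fold change of -1.52 in hsEVT, with 1082 of 1086 below 0, where averaged RNA would hold them near the mean. Damaged cells that keep mitochondrial RNA are argued against by a median of -1.15 for the mitochondrially encoded genes. Averaged free RNA as only a part of the counts was not tested and stays open. The broad shift of hsEVT against pEVT, STB and cytotrophoblast genes included, cannot tell it from other causes. Free RNA from libraries rich in EVT and a true state of low RNA content also stay open. No library or count per cell is given, and no biological explanation was tested.

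Long genes and nuclear RNA were higher in mEVT. RNA that is mostly nuclear or unspliced cannot be told apart from other causes here. The rank correlation across genes of gene span and log2 fold change, 0.59, restates the pattern, and no intron counts are given. Mitochondrially encoded RNA, which lies outside the nucleus, was not low. Its median log2 fold change was 0.59 (percentile 95.6, not called), with 0 of 11 genes higher and 0 lower by the rule. Damaged cells that keep mitochondrial RNA were weighed in hsEVT alone and stay open in mEVT. Lower depth as the whole cause is argued against by hsEVT, which has still fewer genes per cell and a correlation of -0.40. Part of that contrast is built in, since mEVT is among the other cells of hsEVT. The correlation was not worked out again without mEVT. Gene span as the whole cause of the high EVT genes is argued against. Their list stayed at percentile 100 among random lists matched, in broad bins, on span as well as on detection. An effect of span in part is not excluded. A property of these cells and an effect of their handling both stay open, and no biological explanation was tested.

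The higher genes of eCTB were largely those of aCTB and qCTB. A mixture or doublets of aCTB and qCTB, which would keep each gene between the levels of both, are argued against. Of 3511 genes detected in at least 25% of the cells of both, 15 had a level in eCTB under 0.5 times the smaller. Under 1 was expected from the spread of the genes about the best mixture (robust SD 0.109 on the log2 scale), and genes that scatter more widely would raise that number. Among the 3511, 0 lay over 2 times the larger, but the filter leaves out genes rare in both. PASD1, one of these, stood at 14.8 times the mean of all cells in eCTB, 0.187 in aCTB and 0.444 in qCTB. ADGRL3, for example, stood at 0.20 times the mean of all cells in eCTB, 1.18 in aCTB and 2.43 in qCTB. The test fixed beforehand decided nothing, since 63 of 564 higher genes (11.2%) lay above 1.5 times the larger level, between its bounds of 5% and 20%. Gain or loss of a whole autosome is argued against, since no autosome's median differed by more than 0.076 on the log2 scale from that of all autosomal genes. Chromosome X, which holds PASD1 and PINCR, was not tested. A cluster of 1 line or library, including a mixture of aCTB and qCTB cells of that line alone, stays open, because the tables name none, and no biological explanation was tested.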
